A study of Drosophila melanogaster with 3 samples.

How the data were processed

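Chromatin immunoprecipitation with sequencing was done on whole embryos (0 to 24 h, mixed sex) of a transgenic *Drosophila melanogaster* line with Ets97D fused to GFP, using an antibody against GFP, per the labels. Chromatin was fragmented by sonication, with a size range of 200 to 800, unit not stated, per the labels. There are 3 samples, labelled biological replicates 1, 2 and 3, which form 1 group. Replicate numbers are those of the labels.

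The files used are region lists of the narrowPeak type. Per the file headers (the text file deposited beside each sample's lists), each replicate has a list of peaks and background derived from that replicate's alignment and a control. A further list of the same kind was derived from the alignments of all replicates, and an optimal IDR thresholded set was derived from these lists. All exist on the dm6 and dm3 builds. The signal in column 7 is the authors' value per region, from ChIP against control per the file headers; its scale is not stated, and it is higher in the pooled list than in single replicates. The −log10 q value in column 9 is the authors' own per region and was used only to describe the lists. It reached at most 4.00 in the dm6 optimal set, where 599 of 5595 peaks lay below the maximum. The aligner, the peak caller, their versions, the IDR threshold and the duplicate filter are not given in the sources used here. The lists hold no read counts, so the depth per sample is unknown and no interval for the counting error of a signal can be given. Control libraries and signal tracks were not analysed here, so the background was taken from the lists and the genome.

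The authors' regions were sorted by signal. Summits are the deposited start plus the summit offset, written 1-based. The optimal peaks were identical in position and signal to 5595 pooled regions, and these were the 5595 of highest signal. The 5595 pooled regions of lowest signal, none of them in the optimal set, served as background. For each replicate the 5595 regions of highest signal were used. A region was shared when the summits lay within 150 bp. Signals were given relative to the median of a replicate's 5595 strongest regions when replicates were averaged.

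Genome sequence and gene models were the Release 6 assembly with the NCBI sequence and the Ensembl annotation. Region ends and gene ends on all 7 chromosome arms lay within the lengths of that assembly. No coordinates were converted between builds, and dm3 was used only for counts of regions and for signals. Promoters were the 500 bp either side of each annotated TSS of a protein-coding transcript; outside them, summits were assigned in the order 5' UTR, coding exon, 3' UTR, intron, intergenic.

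The 18 gene lists, the panel of 12 words, the tests and the rule for named genes were set before the data were examined. The rule named the 25 strongest promoter peaks with a strongest-set summit of all 3 replicates within 150 bp, with every gene whose TSS lay within 500 bp. It also named Ets97D, up to 4 members of each list with the strongest promoter peak and up to 2 members, in alphabetical order, without one, and the 5 strongest peaks over 2000 bp from a TSS. List names that the annotation did not hold were replaced through unique synonyms; 777 genes matched 792 names, and names with no unique match were left out. Lists hold some genes in common, such as subunits of succinate dehydrogenase.

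Words were sought on both strands within 50 bp of the summit and in a window of the same width centred 500 bp upstream or downstream, the side drawn at random with a fixed seed, and compared by the exact McNemar test. Gene lists were compared with all other protein-coding genes by Fisher's exact test with conditional odds ratios. Shares have Wilson 95% intervals. Chance overlap came from 1000 circular shifts along each chromosome, and differences of medians from 100000 permutations. Chromosomes were compared by the exact binomial test against their share of start site positions. Tests were two-sided, except those by circular shifts, which asked only whether shifted sets reached the observed share. P-values called adjusted were adjusted by Benjamini-Hochberg within their family, and the others are unadjusted. Tests over peaks or genes treat these as units, not the replicates. Copies of summit windows in the genome were sought with BLAST 2.17.0 at 90% identity over 90% of the window. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

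The procedures were tested on simulated data. When 60.2% of 5595 summits were planted as shared, 60.8% were found shared. For the ETS word, planting raised the share to 5.33% of 5595 windows, of which all were found, and without planting the exact McNemar p was 0.694. Of lists with a planted share of bound members among 13968 genes, 97% were called, and 1.57% of lists with none were. In the scan of 2080 words of 6 bases, 0 were called without planting. Both sides of the simulated word tests were random genomic windows, so they do not cover differences in base composition between summits and flanks.

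Alternatives were other distances to the TSS, other start site sets, other words, windows and flank distances, stricter or merged peak sets, other gene backgrounds, other overlap rules and each replicate left out. For tests on the optimal peaks, leaving out 1 replicate meant keeping the peaks with a strongest-set summit of both others within 150 bp. Such sets held 4264 to 4371 of 5595 peaks, whose positions and signals still came from all 3 replicates. Alternatives of replicate agreement used 99 shifts each and those of signal differences 20000 permutations. Promoter shares on dm3 were not computed, since no annotation of that build was used here.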

Results

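The series measured where Ets97D binds the genome of *Drosophila melanogaster* embryos. Ets97D, also called Delg, is a transcription factor with an ETS DNA-binding domain, the fly relative of the alpha subunit of mammalian GABP (NRF-2). Transgenic flies carried Ets97D fused at its C terminus to eGFP, and chromatin from whole embryos collected 0 to 24 h after laying was immunoprecipitated with an antibody against GFP and sequenced (ChIP-seq). There was 1 group with 3 biological replicates, so no conditions were compared. The questions the design allows are how well the replicates agree, which genes and regions carry the peaks, and which sequences lie under them.

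On the dm6 build, the deposited lists held 24391 regions for replicate 1, 28843 for replicate 2 and 29122 for replicate 3, each a mixture of peaks and background. The list from the pooled replicates held 27625 regions, and the optimal set that passed the authors' test of reproducibility (IDR, irreproducible discovery rate) held 5595 peaks. The optimal peaks were the 5595 pooled regions of highest signal, down to a signal of 89.1. No read counts were used here, so the sequencing depth is unknown, and signals were compared by rank within a list or relative to each replicate's own median.

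Among the named promoters, those of RpL7 and RpL23A, both ribosomal protein genes, held the highest signals in each of the 3 replicates. At the promoter of RpL7, a protein of the large ribosomal subunit, the signal was 69.9 ± 2.58 (SD, n = 3) times the median of each replicate's 5595 strongest regions. It was 65.4 ± 3.20 times that median at RpL23A and 60.6 ± 1.67 times at RpL14. At a mid-ranking promoter such as that of eag, which encodes a potassium channel, the ratio was 1.02 ± 0.0505 (SD, n = 3).

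Among the 5595 strongest regions of each replicate, a share of 79.2% was common to replicates 1 and 2, 79.7% to replicates 1 and 3, and 77.7% to replicates 2 and 3 (summits within 150 bp). The mean was 78.9% ± 1.05 (SD over 3 pairs). Random circular shifts of one set along each chromosome gave 1.23%, 1.23% and 1.23% on average and at most 1.97% (permutation p = 0.001 for each pair, the smallest that 1000 shifts can give). A further run of 99 shifts, with the 3 pairs averaged, reached at most 6.29%. Across the regions that replicates 1 and 2 shared, Spearman's rho of the signals was 0.793; regions are not independent replicates. Of the optimal peaks, 3925 (70.2%) had a strongest-set summit of all 3 replicates within 150 bp. This share was 99.4% in the strongest quintile of the peaks and 9.83% in the weakest. With the replicates' full lists in place of the strongest sets, 98.5%, 98.4% and 98.9% of the optimal peaks had a region in replicates 1, 2 and 3.

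Peaks of Ets97D-eGFP lay mostly at promoters, and the 3 strongest promoter peaks were at ribosomal protein genes. The highest promoter peak, with a signal of 11499.9, covered 2L:10200664-10201466 (dm6) between RpL7 (FBgn0005593) and Ripalpha, its summit at 24 bp from the nearest transcription start site (TSS; negative positions are upstream). RpL23A (FBgn0026372) followed with a signal of 10751 at 3L:1668336-1669119, summit at -109 bp, and the start site region of RpL14 and Nelf-E with 9954 at 3L:8600597-8601410. Of the 25 strongest promoter peaks found in all 3 replicates, 13 had a TSS of a ribosomal protein gene within 500 bp, and 23 had their summit upstream of the nearest TSS. RpS27 had a signal of 8499, RpL30 of 7327, RpL41 of 7299 and RpL19 of 6672, while RpL13A, RpLP0, RpS25, RpL22, RpL37A and RpL23 lay between 4169 and 5849.9.

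The other 12 promoters in this set belonged to genes of varied function. Hsp83, the fly Hsp90 chaperone, had a signal of 6012, Nacalpha, a subunit of the nascent polypeptide-associated complex, 5507, the translation elongation factor eEF1gamma 5180 and the translation factor eEF5 4806. Alg3, a mannosyltransferase of N-glycan synthesis, had a signal of 6353, lace, a subunit of serine palmitoyltransferase, 5850.35, and yps, a Y-box RNA-binding protein, 5284. CG6966 ranked 4 with a signal of 9839 at 3R:15095485-15096212, and tzn with 5900.45, Regnase-1 with 5847, goe with 4379 and CG5805 with 4333 completed the set.

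Of the 5595 optimal peaks, 4118 (73.6%, Wilson 95% interval 72.4 to 74.7%) had their summit within 500 bp of a protein-coding TSS. The share was 73.5% in replicate 1, 75.8% in replicate 2 and 71.0% in replicate 3 when each replicate's own 5595 strongest regions were used, a mean of 73.5% ± 2.38 (SD, n = 3). Circular shifts of the summits gave 11.5% on average and at most 25.7% (permutation p = 0.001, the smallest that 1000 shifts can give). Among the 5595 pooled regions of lowest signal the share was 15.9%, an odds ratio of about 15 (95% interval 13.4 to 16.1; two-sided Fisher's exact test, p too small for the software to hold). Intervals cover counting error over peaks only.

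Promoter summits sat just upstream of the start site. Their median position relative to the nearest TSS was -52 bp, with quartiles of -108 and -15 bp, and 82.4% lay upstream. Introns held 840 optimal peaks (15%), intergenic sequence 510 (9.12%), 3' UTRs 73, 5' UTRs 29 and coding exons 25, all counted outside the 500 bp promoter zone. Coding exons held 0.447% of optimal peaks and 16.1% of the lowest-signal regions. Median signal was 173 at promoter peaks and 133 at the other 1477 (difference 40.0, permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 2e-05 over 2 comparisons).

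**Figure D1:**
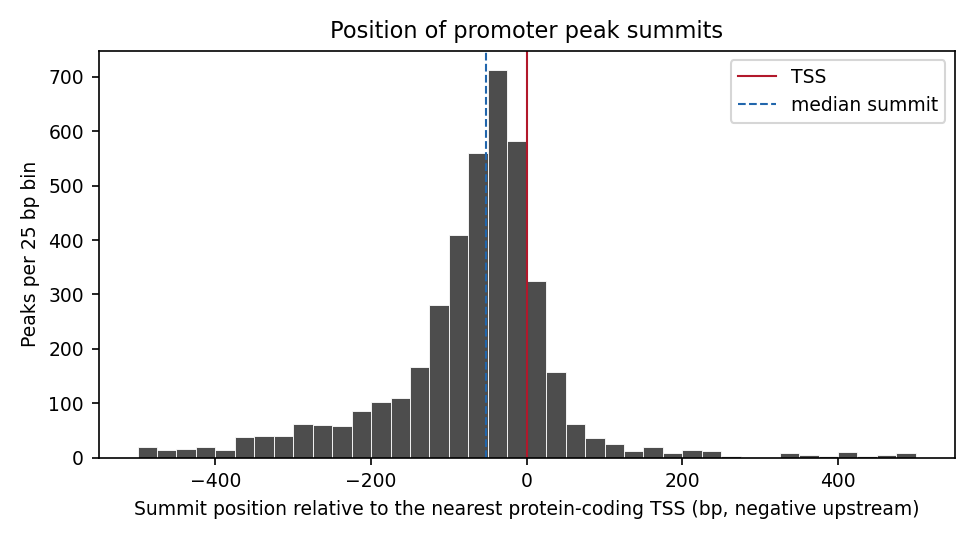
Number of promoter peaks (y axis, per 25 bp bin) by the position of the summit relative to the nearest protein-coding TSS (x axis, bp, negative values upstream), for 4118 optimal peaks. The solid line marks the TSS and the dashed line the median summit, at -52 bp.

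A smaller class of peaks lay far from protein-coding start sites, 814 of them over 2000 bp from any such TSS. Start sites of other gene types were not counted here. With those of all annotated genes, 75.2% of the optimal peaks lay within 500 bp of a TSS, in place of 73.6%. The strongest of these, at 3R:12121031-12121645, was intergenic, 6827 bp from the TSS of CG4702, and ranked 19 of all peaks with a signal of 5316. The next were a coding exon peak at 3L:6124506-6125160 nearest l(3)mbn (signal 2753), an intergenic peak at 2L:9490744-9491202 nearest Gdi (2450.32), a coding exon peak at 2L:11816311-11816834 nearest CycY (2311) and an intergenic peak at 2R:15762204-15762696 nearest Zasp52 (1997). All 5 held the ETS word CCGGAA within 50 bp of the summit.

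Most genes of each housekeeping list carried a promoter peak, and 5 of the 7 lists of tissue or stage genes were below the remaining genes. Of 86 cytosolic ribosomal protein genes, 84 (97.7%) had a promoter peak, and the share was 97.7% ± 0 (SD, n = 3) over the replicates' own regions. The exceptions were RpL10Aa and RpS10a, paralogs of other ribosomal protein genes. At the other end, 1 of 120 odorant and gustatory receptor genes (0.833%) and 2 of 117 cuticle protein genes (1.71%) had one. Over all protein-coding genes, 5097 of 13968 (36.5%) had a summit within 500 bp of a TSS.

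The 5 mitochondrial lists were all higher than the remaining genes. Subunits of respiratory complexes II to V had a promoter peak in 30 of 37 cases (81.1%; 80.2% ± 4.13, SD, n = 3), led by COX6B with a signal of 715 and ox, a subunit of complex III, with 594. ATPsynC, the ring subunit of ATP synthase, had 519 and blw, its alpha subunit, 497, while ATPsynG and ATPsyndelta had no promoter peak. The mitochondrial ribosome had 57 of 75 genes (76.0%; 72.0% ± 3.53), among them mRpS23 with a signal of 833, mRpL41 with 832, mRpL23 with 783 and mRpS16 with 751; mRpL14 and mRpL3 had none. The tricarboxylic acid (TCA) cycle had 14 of 17 (82.4%; 84.3% ± 3.40), including Idh3b, a subunit of isocitrate dehydrogenase, with 363, Fum1, a fumarase, with 292, Ogdh with 274 and mAcon1, an aconitase, with 270.4; Idh and Pdha had none.

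Complex I had the lowest share of the mitochondrial lists, 24 of 39 genes (61.5%; 63.2% ± 3.92, SD, n = 3). ND-51 had a signal of 460.08, ND-B18 440.4, ND-MWFE 319 and ND-ASHI 292, and ND-20L and ND-23 had no promoter peak. The list also counts genes whose names mark them as like another subunit, ND-20L among them. None of these had a promoter peak, which lowers the share of the list. Genes for mitochondrial genome upkeep and import had a peak in 19 of 25 cases (76.0%; 73.3% ± 6.11), with signals of 282 at Tim10, 225 at Tom7, 217 at PolrMT, the mitochondrial RNA polymerase, and 188 at Hsc70-5. TFAM, which packages mitochondrial DNA, and Tim13 had no promoter peak. Some of these summits lie between divergent or overlapping genes, so that 1 peak counted for each gene with a TSS within 500 bp; the COX6B summit, for instance, was shared with CG33932, Rpp20 and CG18809. With each summit given to its nearest TSS only, the share of the mitochondrial ribosome was 41.3% and its odds ratio 1.92 in place of 5.56, and the other 10 higher lists had shares from 51.3% (complex I) to 94.2% (cytosolic ribosome).

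The other housekeeping lists were higher as well. The proteasome had 28 of 32 genes (87.5%; 78.1% ± 3.12, SD, n = 3), with signals of 439 at Rpn9 and 431 at Rpn6, and none at Prosalpha1 and Prosbeta2. The spliceosome had 26 of 31 (83.9%; 81.7% ± 1.86), led by SmD3 with 922 and Prp3 with 486, and LSm-4 and Prp31 had none. Glycolysis had 11 of 13 (84.6%; 74.4% ± 4.44), led by Pglym78 with 599 and Pgk with 522, and Gapdh1 and Hex-C had none. DNA replication had 26 of 33 (78.8%; 78.8% ± 6.06), led by dup, the fly Cdt1 licensing factor, with 754 and dpa with 425, and Fen1 and Mcm3 had none. The cell cycle list had 24 of 31 (77.4%; 72.0% ± 6.72), led by CycB with 488 and CycB3 with 473, and Bub1 and Myt1 had none.

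Of the lists of tissue and stage genes, embryonic patterning, neuron, blood and fat body, receptors and cuticle were lower. Embryonic patterning genes had 3 of 39 (7.69%; 9.40% ± 1.48, SD, n = 3): cad, a homeobox gene of the posterior, with a signal of 421, bcd with 229 and wg with 121, and the Hox genes Abd-B and Antp had none. Neuronal genes had 3 of 22 (13.6%): elav with 294, Syx1A with 239.6 and eag with 174, and ChAT and Gad1 had none. Blood and fat body genes had 1 of 24 (4.17%; 2.78% ± 2.41), the scavenger receptor gene crq with a signal of 127, with Adh and Col4a1 among those without. The receptor peak was that of Gr63a, whose summit was shared with Lamtor4, and the cuticle peaks were those of Lcp9, shared with CG3594, and Cpr62Ba.

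Muscle and germline lists did not pass the test. Muscle genes had 5 of 21 (23.8%; 20.6% ± 2.75, SD, n = 3), among them Tm1 with a signal of 242, sls with 232, Msp300 with 218 and Mef2 with 209, and Act57B and Act87E had none. Germline genes had 8 of 15 (53.3%; 53.3% ± 6.67). The strongest of these was bgcn, a partner of bam in germ cell differentiation, with 3772 at 2R:23858458-23859069, rank 39 of all peaks. It was followed by tej with 416, zpg with 339.7 and bam itself with 216, and AGO3 and aub had none.

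Of the 18 lists, 11 were higher and 5 lower than all other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 18 lists). Odds ratios among the higher lists ran from 2.79 for complex I (95% interval 1.40 to 5.73, exact test, adjusted p = 0.00266) to 74.3 for the cytosolic ribosome (19.9 to 624, adjusted p = 2.94e-33). Among the lower lists they ran from 0.0144 for the receptors (exact test, adjusted p = 1.22e-21) to 0.274 for neuronal genes (0.0520 to 0.933, adjusted p = 0.0295). The neuronal call was lost when the optimal peaks were limited to those with a strongest-set summit of both replicates of any 1 pair. The adjusted p was 0.111 in each case, and between 0.00151 and 0.535 over its 11 alternatives (Fisher's exact test). These sets held fewer peaks, 4264 to 4371 of 5595. With the 50% of peaks of highest signal, the calls of complex I, upkeep and import, the spliceosome and glycolysis were lost. Against only those genes with any pooled region within 500 bp of a TSS, 5 lists stayed higher: complex I, the TCA cycle, upkeep and import, DNA replication, the cell cycle and glycolysis did not, nor did blood and fat body genes stay lower.

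**Figure D2:**
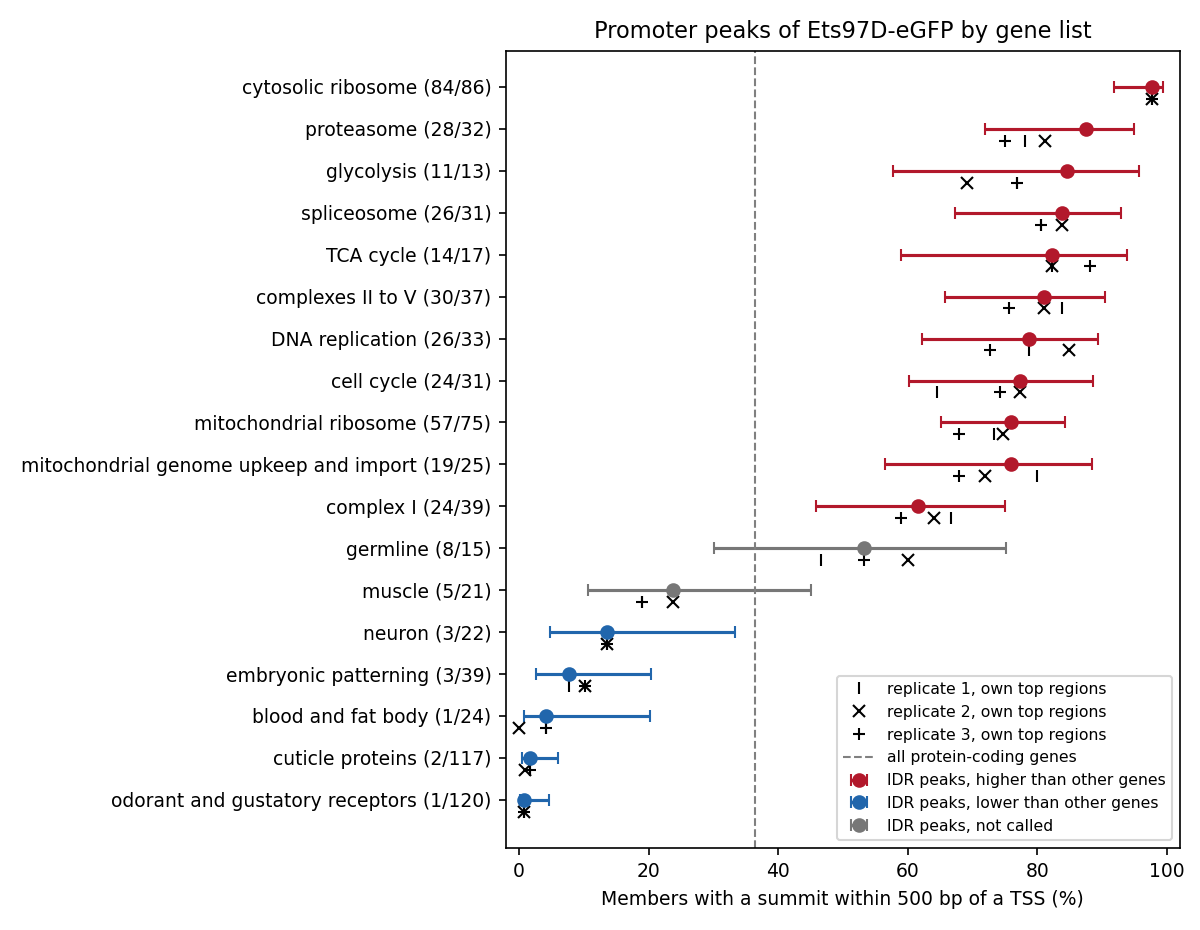
Share of each list's genes with a summit within 500 bp of a TSS (x axis, %). Circles are the optimal peaks with Wilson 95% intervals, coloured by the test against all other protein-coding genes, black marks are the 3 replicates' own strongest regions, and the dashed line is the share over all protein-coding genes, 36.5%; 11 lists lie above it and 5 below it by the test.

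The 84 ribosomal protein promoters also stood apart in strength. Their median signal was 2106 and their median rank 78.5 of 5595, and 49 of the 100 strongest peaks were theirs, a count chosen after the data were seen. Median signals of the other 10 higher lists lay between 151 at complex I and 242 at the cell cycle list, near the 173 of all promoter peaks.

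Words of promoter elements were more frequent under the summits than the ETS word. TATCGATA, the DNA replication-related element (DRE) that the factor DREF binds, was within 50 bp of the summit in 427 peaks (7.63%) and in 0.322% of windows 500 bp away. GGTCACAC, the core promoter element Motif 1, was in 325 peaks (5.81%) against 0.465%, and CGATA, the core bound by the insulator protein BEAF-32, in 1765 (31.5%) against 12.2%. TATCGATA contains CGATA, so each peak with TATCGATA also counts for CGATA. The ETS word of the GABP type, CCGGAAG, was in 70 peaks (1.25%, Wilson 95% interval 0.992 to 1.58%) against 0.608%. Over the replicates' own regions, the share with CCGGAAG was 1.14% ± 0.0619 (SD, n = 3) and that with TATCGATA 7.16% ± 0.105.

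Of the 12 words fixed beforehand, 7 were more frequent and 1 less frequent at the summits (exact McNemar test, two-sided, Benjamini-Hochberg adjusted over 12 words). The adjusted p was 0.00107 for CCGGAAG, 1.10e-102 for TATCGATA, 2.00e-67 for GGTCACAC and 1.21e-132 for CGATA. The TATA word TATAAA (14% against 10.1%), the Ohler 5 E-box CAGCTG (7.58% against 5.34%) and the AP-1 word TGACTCA (1.07% against 0.518%) were also higher, and the GAGA factor word GAGAGAG was lower (1.32% against 2.04%). The early embryonic Zelda word CAGGTAG, the E-box CACGTG, GCGCATGC and CTCTTTC did not pass the test. Against the lowest-signal regions, CCGGAAG had an odds ratio of 1.64 (Fisher's exact p = 0.0136) and TATCGATA 25.6 (p = 5.02e-106), while TGACTCA (1.09, p = 0.708), TATAAA (1.11, p = 0.0668) and GAGAGAG (0.820, p = 0.238) did not pass that test.

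The ETS word was more frequent in peaks away from promoters than in promoter peaks. CCGGAAG was in 37 of the 1477 peaks over 500 bp from a TSS (2.51% against 0.406% in their flanks, exact McNemar p = 1.64e-06) and in 33 of 4118 promoter peaks (0.801% against 0.680%, p = 0.609), a difference between the classes by Fisher's exact test (odds ratio 0.314, adjusted p = 3.21e-06 over 4 words). TATCGATA had the opposite distribution, 9.91% of promoter peaks and 1.29% of the others (odds ratio 8.44, Fisher's exact test, adjusted p = 3.11e-34), and so did GGTCACAC, 7.72% and 0.474%. Peaks with CCGGAAG had a median signal of 186 and those without it 162, a difference that did not pass the test (permutation p = 0.0659). It passed within promoter peaks alone (permutation p = 0.0471) and on mean ranks (p = 0.0129).

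Calls of this kind were common: of all 2080 words of 6 bases, 498 were more frequent and 720 less frequent at the summits by the same test, so a call alone does not single out a word. TATCGA ranked first, in 1140 summit windows and 210 flanks (exact McNemar test, adjusted p = 4.34e-161). In the peaks over 500 bp from a TSS the first rank went to CCGGAA, in 116 windows and 31 flanks (exact McNemar test, adjusted p = 3.49e-10), followed by CGGAAA (189 and 87). CCGGAA was also frequent in the strongest peaks, a grouping chosen after the data were seen. It was in 38 of the strongest 100 (38% against 2% in flanks, exact McNemar p = 1.49e-09), and in 8 of the 25 promoter peaks named above, those of Alg3, tzn, lace, RpL13A, yps, eEF1gamma, goe and CG5805. In the strongest quintile of peaks the share was 8.49% against 3.57% in flanks (exact McNemar p = 2.06e-06), and in the other 4 quintiles it lay between 3.49% and 4.29% against 2.86% to 4.02% in flanks.

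**Figure D3:**
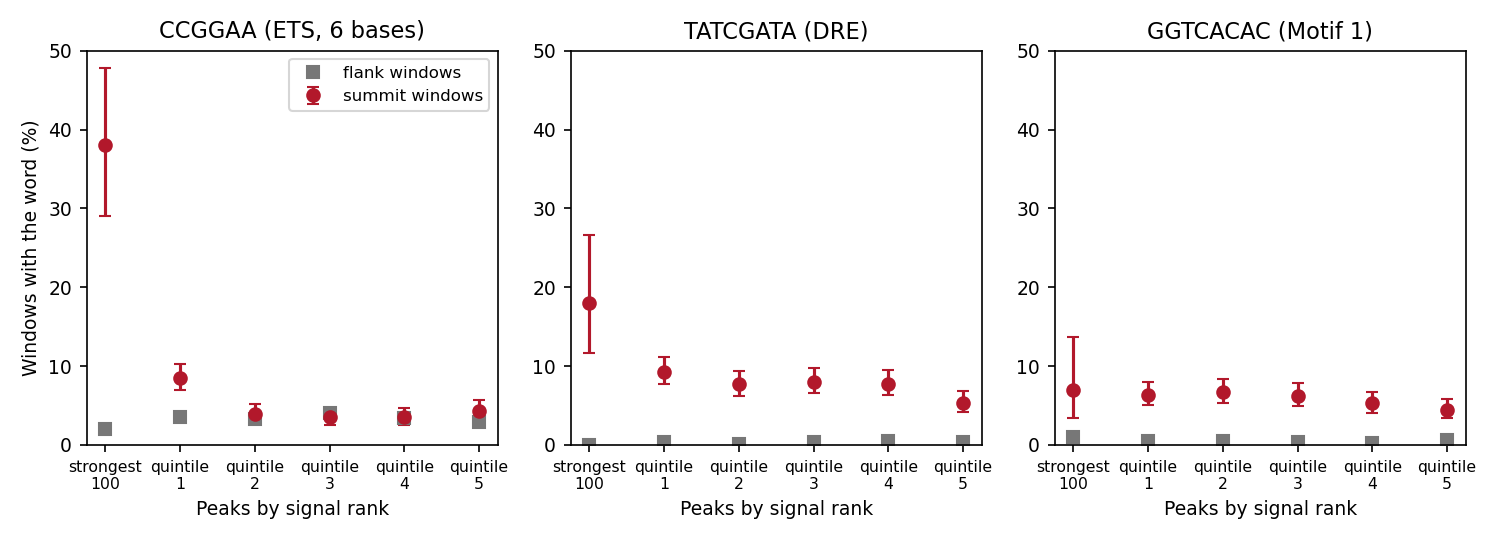
Share of windows (y axis, %) with CCGGAA, TATCGATA or GGTCACAC, within 50 bp of the summit (circles, Wilson 95% intervals) and 500 bp away (squares), for the strongest 100 peaks and for quintiles of the 5595 peaks by signal (x axis, 1 strongest). CCGGAA stands above its flanks in the strongest 100 (38%) and in quintile 1 (8.49%), and TATCGATA and GGTCACAC stand above theirs in each quintile.

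The single ETS result depended on how the word and window were set. The core GGAA alone was less frequent at the summits, 52.7%, than in their flanks, 57.4%, and with windows of 100 bp either side CCGGAAG was in 1.64% against 1.30% (exact McNemar p = 0.161).

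No chromosome was called as richer or poorer in peaks than its share of start sites. The X chromosome held 1007 peaks (42.8 per Mb), 1.06 times its share of protein-coding start sites, 2L held 1015 (0.965 times) and 3R 1339 (1.01 times). The small chromosome 4 held 51, 1.24 times its share, and the Y chromosome 1, 0.150 times. None of the 7 passed the exact binomial test after Benjamini-Hochberg adjustment (lowest adjusted p = 0.129, for the Y). At an unadjusted p under 0.05 were the X (exact binomial p = 0.0462) and the Y (p = 0.0184).

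At its own locus, Ets97D (FBgn0004510, 3R:26910775-26912886, minus strand) had an optimal peak at its promoter. The flies also carried the tagged transgene, and these lists do not tell signal at the gene's own copy from signal at the transgene. The summit at 3R:26912924 was 38 bp upstream of the TSS, with a signal of 302.8 and rank 915 of 5595. In the replicates' lists the summit nearest the TSS was 38, 36 and 45 bp away and ranked 1050 of 24391, 800 of 28843 and 934 of 29122, with a signal 1.89 ± 0.106 (SD, n = 3) times the median of each replicate's strongest 5595.

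The same experiment was also deposited on the older dm3 build. The optimal set held 5391 peaks there, so that dm6 held 3.78% more. The pooled list held 24614 regions on dm3 and 12.2% more on dm6. Of the optimal dm3 peaks, 10 lay on heterochromatic scaffolds. By arm, dm6 held 3.26% more optimal peaks on 2L, 5.81% more on 3L and 3.07% more on X. The highest signal was 11499.9 on dm6 and 11495.5 on dm3.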

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

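The strongest 100 and strongest 300 peaks, the word CCGGAA and the lists without peaks holding it were alternatives chosen after seeing the data; the others were set before the data were examined. Replicate agreement lay between 61.2% (summits within 50 bp) and 84.2% (any overlap), above the shifted sets in each of the 8 alternatives run, and between 77.7% and 79.7% with 1 replicate left out. The promoter share lay between 63.9% (TSS within 200 bp) and 80.7% (the 50% of peaks of highest signal), above the lowest-signal regions in each of its 10 alternatives. It lay between 75.8% and 78.1% for the optimal peaks with a strongest-set summit of both replicates of a pair. The ETS word CCGGAAG was above its flanks in the other settings run, from 0.697% (word CCGGAAGT, or windows of 25 bp either side) to 10% (strongest 100), but the call ended in promoter peaks alone (0.801%, exact McNemar p = 0.609) and with windows of 100 bp either side (1.64%, p = 0.161), and the direction turned with the GGAA core (52.7% against 57.4%). The cause was not tested. The signal difference for peaks with CCGGAAG, 24.5 in the planned test, passed the threshold within promoter peaks (42.8) and as a difference of mean ranks (487 ranks); the cause was not tested.

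The number of higher gene lists was 7 with the 50% of peaks of highest signal, where fewer peaks were tested, and 5 when the background was restricted to genes with any pooled region; it was 11 in the other 9 alternatives, peaks without CCGGAA included. The cause was not tested. Over 176 tests of the 16 called lists, 159 kept the call, 17 lost it and none turned, and the 2 uncalled lists stayed uncalled in 22; the losses were mainly of complex I, mitochondrial upkeep and import, glycolysis and neuronal genes. Against assembled length in place of start sites, 1 chromosome was called, the Y (0.00670 times its share), and uncalled ratios turned for 2L (1.06), 2R (1.06), 3L (0.956) and chromosome 4 (0.930). In windows of 100 bp either side, 6 words of the panel were called: GAGAGAG and TGACTCA lost their calls along with CCGGAAG, CAGGTAG gained one as lower (0.786%), and uncalled directions turned for CACGTG (3.27%) and GCGCATGC (0.447%). The promoter share with the dm3 annotation was not run. No paired analysis was possible because there is 1 group. The unknown depth limits any statement on weak regions. In the weakest quintile of peaks, 9.83% had a strongest-set summit of all 3 replicates within 150 bp. That share counts only each replicate's strongest regions, not its full list. With the full lists, 98.5%, 98.4% and 98.9% of all optimal peaks had a region in replicates 1, 2 and 3. The full-list shares were not split by quintile.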

Other observations

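The scan of word pairs, the tests of ETS words in the strongest quintile and the strongest 50 peaks, of all other spacings together, the grouping of lists, the spacer bases, the comparison of pairs between peak classes and the values by signal rank were chosen after the results were seen. With 1 group, no explanation was tested against another condition.

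Taken as 1 group, the 5 mitochondrial lists had a promoter peak at 143 of 191 genes (74.9%), and the 6 other housekeeping lists at 199 of 226 (88.1%; odds ratio 0.405, 95% interval 0.231 to 0.698, Fisher's exact p = 0.000534). Without the ribosomal protein genes the other lists stood at 115 of 140 (82.1%), and the difference did not pass the test (odds ratio 0.648, Fisher's exact p = 0.140). The mitochondrial count includes the complex I genes named as like another subunit, none of which had a promoter peak. The ETS word CCGGAA lay within 50 bp of the summit in 1 of the 57 promoter peaks of the mitochondrial ribosome and in 0 of the 24 of complex I, the 30 of complexes II to V, the 14 of the TCA cycle and the 19 of mitochondrial upkeep and import. It was in 16 of the 84 ribosomal protein peaks and 1 of the 11 of glycolysis, but in 0 of the 28 of the proteasome, the 25 of DNA replication, the 24 of the cell cycle and the 26 of the spliceosome, and in 3.62% of all promoter peaks, so its lack is not particular to the mitochondrial lists.

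A small part of the peaks away from promoters held a pair of GGAA cores. Of the 1477 peaks over 500 bp from a TSS, 90 (6.09%) held 2 copies of GGAA on the same strand with 2 bases between them, against 18 of their flanks, 5 times as many (exact McNemar test, adjusted p = 4.01e-11 over 126 combinations of spacing, orientation and peak class). It was the only one of the 126 to pass. In promoter peaks the same pair was in 48 summit windows and 29 flanks (exact test, adjusted p = 0.776), a lower share than in distal peaks (odds ratio 0.182, 95% interval 0.125 to 0.262, Fisher's exact p = 4.27e-22). Among the strongest 300 peaks it was in 9 of 251 promoter peaks, against 1 of their flanks (exact McNemar p = 0.0215), and in 6 of 49 distal peaks, against 1 (p = 0.125); the classes differed (Fisher's exact p = 0.0218). Among the strongest 100 it was in 5 of 81 and 3 of 19, and the difference did not pass the test (Fisher's exact p = 0.174). Among the 100 pairs in these windows, the 2 bases between were AC in 56 and GC in 21, and the base before the first G was C in 73. The intergenic peak nearest Gdi, the coding exon peak nearest CycY and the Alg3 promoter held the pair, and the distal peaks nearest CG4702, l(3)mbn and Zasp52 did not. Distal peaks with the pair had a median signal of 153 and those without it 133 (permutation p = 0.0297). Over all 1477 peaks over 500 bp from a TSS, with or without the pair, words such as GCGCCA were also more frequent than in their flanks (126 and 49 windows, exact McNemar test, adjusted p = 6.95e-07).

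The first pattern weighed is that most peaks lack the ETS word, which weak peaks near the threshold do not wholly explain: CCGGAAG was in 2.14% and CCGGAA in 8.49% of the strongest quintile. Strength still matters, since CCGGAAG was in 10% and CCGGAA in 38% of the strongest 100, against 0% and 2% of their flanks. For a narrow window or word, CGGAA was sought within 250 bp of the summit. Peaks differed from windows 2000 bp away by -1.18 percentage points (95% interval -3.00 to 0.643), so no excess was seen. CGGAA was already in 56.8% of the far windows, so added sites in part of the peaks would change the share little. The test thus cannot exclude this explanation. It also stays open that Ets97D-eGFP, or the assay, may mark active promoters that have no ETS site. Genes with CCGGAA within 500 bp of a TSS had a promoter peak more often, 39.2%, than genes lacking it, 35.0% (odds ratio 1.20, Fisher's exact p = 7.91e-07). Any TSS of a gene could supply the word or the peak, and the number of start sites per gene was not adjusted for. At promoter summits CCGGAA was in 3.62% of windows and 3.91% of flanks (exact McNemar p = 0.528). Among genes lacking CCGGAA within 500 bp of a TSS, 107 of 126 members of the 6 housekeeping lists that are not mitochondrial had a promoter peak, and 34.3% of all other genes, mitochondrial lists included (odds ratio 10.8, Fisher's exact p = 2.75e-31), which does not tell recruitment by other factors from signal that any tagged protein could give.

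The second pattern is the GGAA pair with 2 bases between. Copies at 90% identity over 90% of the window are argued against: 0 of the 90 peaks lay in an annotated transposable element or shared their window with another peak (Wilson 95% upper limit 4.09%). Over all 5595 peaks the share was also low, 0.232%. Shorter or more diverged repeats were not sought. For base composition, the outcome that had been written beforehand for it being the cause did occur, since the ratio of 5 at 2 bases was not the highest: 19 bases gave 8, from 16 and 2 windows (exact test, adjusted p = 0.0827; the demand that such a spacing also pass this test was added after its value was seen). Summed over the other 20 spacings, the ratio was 1.38 (95% interval 1.12 to 1.70), under the 2.99 at the lower end of the interval for 2 bases, which argues against composition shared by all spacings. Base composition thus stays open in part, and so does the hypothesis that the pair may be a joint site for 2 ETS domains, which these lists do not test.

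The third pattern is the rank of ribosomal protein promoters, with 23 of the 50 strongest peaks. More than one copy of the bound sequence on the 7 assembled chromosome arms is argued against. Of the 84 peaks, 0 had another copy of the summit window there (Wilson 95% upper limit 4.37%). Over all 5595 peaks the share was also low, 0.197%. Copies outside these arms, or merged into 1 in the assembly, were not sought. ETS words may contribute at part of them: CCGGAA was in 19.0% of these peaks and in 3.30% of other promoter peaks, which are of all strengths (odds ratio 6.89, 95% interval 3.63 to 12.4, Fisher's exact p = 2.97e-08). Against other peaks of like rank there was no such excess: in the strongest 50 the word was in 1 of 23 (4.35%) and 14 of 27 (Fisher's exact p = 0.000401), in the strongest 100 in 12 of 49 and 26 of 51 (p = 0.00772), at ranks 51 to 100 in 11 of 26 and 12 of 24 (p = 0.777), and in the strongest 300 in 16 of 72 and 46 of 228 (p = 0.739). High transcription of these genes stays open as an untested explanation.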
